A study of Oncorhynchus mykiss with 14 samples.

How the data were processed

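Whole ovaries of rainbow trout (Oncorhynchus mykiss) at 5 stages were profiled on 14 single-colour Agilent miRNA arrays. Per the labels, total RNA was extracted with Tri-Reagent, purified on a column kit for miRNA, and 200 ng was labelled with cyanine 3 by end ligation. The series design calls the 2 or 3 samples of a stage biological replicates. The stages were immature (pre-vitellogenic ovary, 5 months old, 3 arrays), mid-vitellogenesis (3), late vitellogenesis (3), post-vitellogenesis (2) and mature ovary with meiotic maturation under way (3).

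Per the file headers, Agilent Feature Extraction 10.7.3.1 made the scanner files, and the processed signal in them is an intensity after background subtraction, not normalized between arrays. The spot and local background medians in these files are raw intensity values per the file headers, and further columns mark spots well above background, uneven spots and saturated spots. The deposited series table holds log2 values with nearly the same distribution in every column, at most 0.072 apart at any rank. Its making is not given in the sources used here, and it was checked against the scanner files. For 10 of its 14 columns the rank correlation with the raw spot medians of the array's own file exceeded 0.999, so these columns rank spots as the spot median without background subtraction does, and the near equality of the columns points to a normalization between arrays. The 3 mature columns matched one another's arrays, and the column of post-vitellogenesis array 1 matched its own file only with a rank correlation of 0.631. The median of each column of the deposited values was 5.32, 5.30 and 5.32 for immature arrays 1 to 3, 5.31, 5.32 and 5.30 for mid-vitellogenesis, 5.33, 5.33 and 5.32 for late vitellogenesis, 5.32 and 5.33 for post-vitellogenesis, and 5.32, 5.33 and 5.30 for mature ovary. The direction of that table is thus known for the 10 columns, and how the post-vitellogenesis 1 column was made stays unknown. The scanner files were therefore used, and the deposited table served as an alternative.

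Each array held 62964 spots, of which 2164 were controls. The other spots carried 8686 probes under 3297 miRNA names from miRBase species, among them zebrafish (Danio rerio), and each probe had 4 to 16 spots with a median of 8. A probe for another species' miRNA can bind a trout miRNA of similar sequence, and probe sequences were not analysed here. Control spots and spots marked as outliers were left out. Each array was scaled by its 75th percentile over the 452 probes well above background on all 14 arrays. Values were then floored at the 1st percentile of the scaled signals well above background, 3.55 on the log2 scale, put on the log2 scale, and averaged over the spots of a probe. A probe was kept if most of its spots were well above background on every array of at least 1 stage, which left 681 probes and 292 names. Of these probes 215 were named for zebrafish miRNAs and 466 for those of other species, among them 146 for mouse, 87 for chicken, 83 for human and 59 for platypus. The number of arrays per stage limits the precision of every value.

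Tests used R 4.3.3 with limma 3.58.1, and the data.table package (1.17.8) read the files. A linear model with the 5 stages was fitted to all 14 arrays with limma (lmFit and eBayes). It gave a moderated F-test across the stages and 5 two-sided contrasts, with Benjamini-Hochberg adjusted p over the 681 probes and a threshold of 0.05. Every adjusted p of a miRNA is from limma. Of several probes with 1 name, the one with the highest mean stood for the name. Named miRNAs were the 25 names with the widest range of stage means in the F-test and, per contrast, the 10 largest rises and the 10 largest falls among names past the threshold whose arrays did not overlap between the stages. They also included every measured member of the fixed lists and the 10 brightest names. Where no array of the lower stage was well above background, the fold is a lower bound. It was computed from the higher stage's mean against the lower stage's arrays, each set to the dimmest probe well above background on that array if its value lay below it.

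A total of 25 lists of miRNA families and cell type markers was fixed: let-7, miR-430, miR-202, miR-17-92, miR-200, miR-183 cluster, granulosa list, miR-15/16, miR-23/24/27, the miR-10, miR-99, miR-100 and miR-125 group, miR-30 and miR-26, miR-29, miR-181, erythroid, leukocyte, endothelial, smooth muscle, stromal, skeletal and cardiac muscle, liver, neural, the miR-221 and miR-222 family, the miR-462 and miR-731 cluster, miR-203 with miR-205, and miR-192 with miR-194 and miR-215. The 19 lists with at least 3 measured names were tested with camera in limma at its preset correlation of 0.01. The 95 pairs of list and contrast were adjusted together (Benjamini-Hochberg). Both camera with an estimated correlation and fry served as alternatives. The tests, the lists, the naming rule and most alternatives were fixed before the data were examined.

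The alternatives were other scalings (75th percentile over all probes, median, quantile), normexp background correction with an offset of 50, other filters and floors, 1 value per name, the deposited table, blocks by slide or replicate number, array weights, trend and robust eBayes, fits to the compared stages alone, and leaving out each array. The normexp correction used the spot median. Slides were read from the scanner files: slide 1 held the immature and mid-vitellogenesis arrays and late vitellogenesis 1 and 2, slide 2 held late vitellogenesis 3, both post-vitellogenesis arrays and mature 1 and 2, and slide 3 held mature 3. The pipeline was tested on simulated data with 681 probes, 200 of them changed, in 20 simulations. The simulated noise was normal and independent between probes, with 1 SD per probe for all stages and no slide effect. The shares recovered and false therefore hold for that setting and were not measured for the real arrays. At a log2 change of 1 it recovered 60.8% of the changed probes in the mid-vitellogenesis against immature contrast and 48.7% in post-vitellogenesis against late vitellogenesis. At a log2 change of 2 it recovered 89.5% and 86.0%. Over all simulated sizes of change together, 3.68% and 3.74% of the calls in these 2 contrasts were false.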

Results

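miRNA levels in whole rainbow trout ovary were measured on 14 arrays, with 3 arrays per stage except for post-vitellogenesis with 2. Between 557 and 938 of the 8686 probes per array were well above background, 7.69% on average. The median coefficient of variation among spots of a probe was 38.1% on late vitellogenesis array 3, 41.7% on post-vitellogenesis array 1 and 16.1% on post-vitellogenesis array 2, the arrays that the scanner software marked for evaluation. The other arrays ranged lower, with 5.96% on late vitellogenesis 1 and 11.3% on mid-vitellogenesis 2. No spot was saturated. The brightest name was miR-1937b, followed by miR-451, which is abundant in red blood cells. The brightest names also included the endothelial miR-126a and let-7a. Across the 681 probes, which are not independent replicates, arrays of the same stage correlated with r between 0.938 and 0.985 (median 0.967). Immature arrays correlated with those of the other stages with a median r of 0.868, and arrays of 2 different later stages with a median of 0.946. The first principal component held 48.3% of the variance, and the next held 13.4%.

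Across the 5 stages, ovarian miRNAs parted mainly between the immature stage and all later ones. miR-2184 stood at a log2 signal of 6.03 ± 0.43 (SD, n = 3) in immature ovary and reached 10.87 ± 0.03 (n = 2) in post-vitellogenesis. miR-29b, whose family targets collagen and other matrix mRNAs, went from 6.66 ± 0.69 (n = 3) to 11.08 ± 0.40 (n = 2) over the same stages. miR-192, an miRNA of gut and kidney epithelium, was brightest in immature ovary with 9.38 ± 0.91 (n = 3) and dimmest in post-vitellogenesis with 4.74 ± 0.53 (n = 2). The gonad-enriched miR-202* was highest in mid-vitellogenesis with 13.01 ± 0.58 (n = 3), and miR-221 in mature ovary with 10.21 ± 0.06 (n = 3). The erythroid miR-144 and miR-451 were highest in post-vitellogenesis, with 11.75 ± 1.04 and 15.64 ± 1.16 (n = 2). By the moderated F-test 328 of 681 probes and 140 of 292 names differed among the stages. The adjusted p was 9.47e-07 for miR-2184, 2.81e-05 for miR-192, 9.63e-06 for miR-29b, 7.44e-05 for miR-202*, 0.0363 for miR-144 and 0.0432 for miR-451. Of the 140 names, 52 had their highest mean in immature ovary, 17 in mid-vitellogenesis, 9 in late vitellogenesis, 37 in post-vitellogenesis and 25 in mature ovary. The lowest mean was that of immature ovary for 67 names, and that of the 4 later stages in their order for 16, 14, 22 and 21. Leaving out 1 array ended the F-test call of miR-144 for 9 of the arrays, with adjusted p up to 0.16, and that of miR-451 for 10, with adjusted p up to 0.126, both highest without post-vitellogenesis 1. The F-test count was 188 when each array was scaled by all probes, 165 with normexp background correction and 157 with no filter on dim probes.

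**Figure D1:**
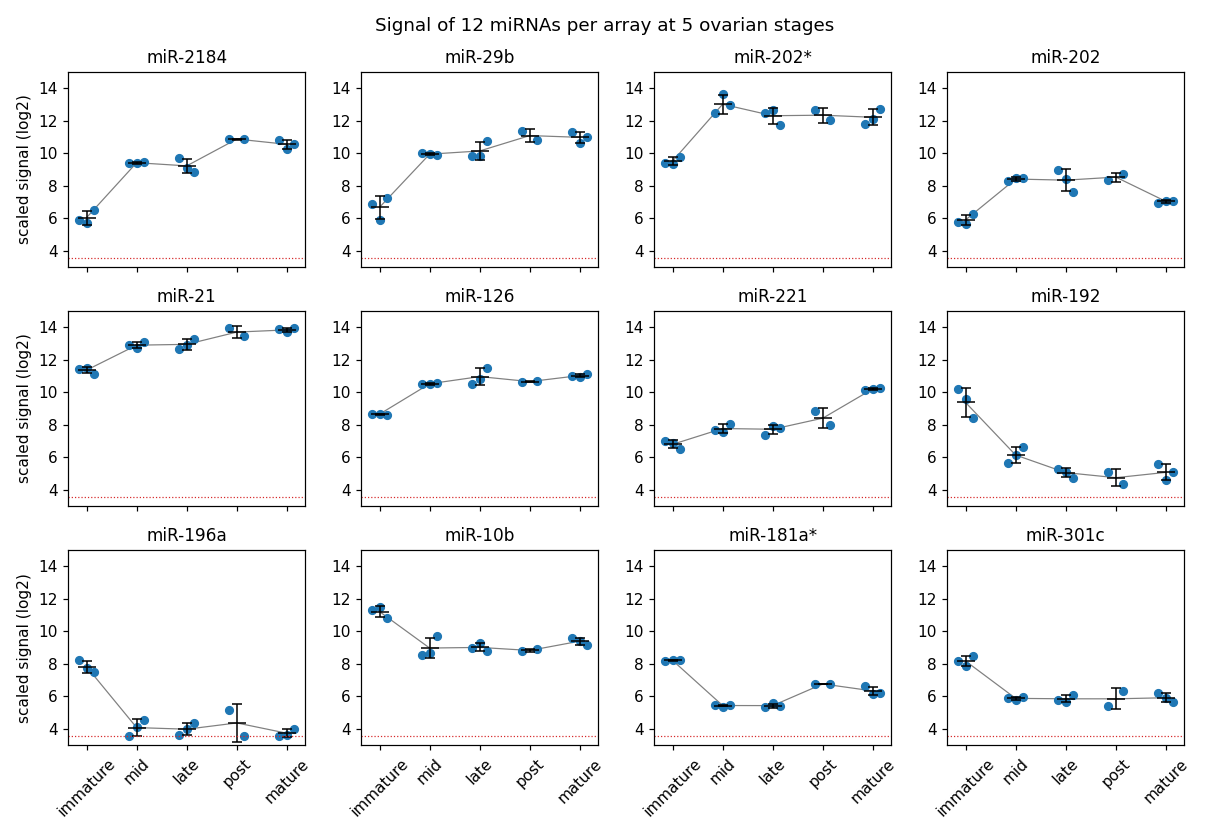
Log2 scaled signal (vertical axis) of 12 miRNAs at the 5 ovarian stages (horizontal axis). Points are arrays, black bars the mean ± SD of a stage, grey lines join the means, and the red dotted line is the floor of 3.55; miR-29b stood at 6.66 in immature ovary and 10.97 in mature ovary, and miR-221 rose from 8.41 in post-vitellogenesis to 10.21 in mature ovary.

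The comparison of mid-vitellogenesis with immature ovary asks which miRNAs differ in whole ovary before and during yolk uptake. The labels give an age only for the immature stage. Here and in mature against immature ovary, stage and age therefore cannot be told apart. The gonad-enriched miR-202* rose by 3.50 ± 0.36 (SE) on the log2 scale, from 9.50 ± 0.25 to 13.01 ± 0.58 (SD, n = 3 each), and miR-202 rose from 5.89 ± 0.32 to 8.40 ± 0.13. miR-2184 rose by 3.38 ± 0.26, miR-29b by 3.27 ± 0.35 and miR-29a by 2.99 ± 0.21. miR-7, known from endocrine cells, rose by 2.37 ± 0.27 and miR-21 by 1.54 ± 0.22. miR-196a, encoded in Hox clusters, showed a change of -3.75 ± 0.40, with 2 of the 3 mid-vitellogenesis arrays above background. miR-192 changed by -3.24 ± 0.44, miR-181a* by -2.78 ± 0.17, miR-301c by -2.30 ± 0.26 and miR-10b by -2.24 ± 0.30. Adjusted p was 2.09e-05 for miR-202*, 2.04e-06 for miR-2184, 2.42e-05 for miR-196a and 9.48e-07 for miR-181a*. In all, 290 of 681 probes passed, 182 higher and 108 lower in mid-vitellogenesis. They stood for 123 names (74 higher, 49 lower), 92 of them with more than a 2-fold difference. The median of all probes was itself 0.24 higher in mid-vitellogenesis under the scaling used, and 0.46, 0.15, 0.00 and -0.13 under the scalings by all probes, by the median, by quantiles and with normexp. List medians are therefore also given relative to it. Every immature and mid-vitellogenesis array lay on slide 1. A fit to that slide alone called 306 probes (185 higher, 121 lower), and the fit with slide as a block called 292. All 60 calls among the named miRNAs passed in both. By design neither fit can change the differences themselves, only their SEs, so this is no independent support. With normexp background correction 135 probes passed, and 150 with no filter on dim probes.

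Among the lists, 4 of the 5 measured names of the miR-29 family rose, and 4 adjusted over the list alone. The list median was 2.95, or 2.71 above that of all probes, and stayed 2.95 with names not well above background at their bounds. miR-29c had 1 of 3 immature arrays above background and rose by 2.95 ± 0.24, and miR-29d, not well above background on any immature array, was at least 3.63-fold higher. All 4 names of the endothelial list rose, and 4 adjusted over the list alone, among them miR-126 by 1.87 ± 0.22 and miR-126a by 1.31 ± 0.20. The 4 were miR-126, miR-126a, miR-126a* and miR-126b*, all names of miR-126, so they are not 4 separate endothelial markers. Camera gave adjusted p = 0.00549 for miR-29 and 0.0211 for the endothelial list, and for both adjusted p = 0.447 with an estimated correlation. The endothelial call also ended without mid-vitellogenesis 1 (adjusted p = 0.0582). In the miR-10, miR-99, miR-100 and miR-125 group, which holds Hox cluster and let-7 neighbours, 8 of 10 names fell, and 8 adjusted over the list alone, with a median of -1.08, or -1.33 relative to all probes. miR-125b in it changed by -0.90 ± 0.20 and miR-10a by -2.11 ± 0.25, while miR-125a differed by -0.24 ± 0.38 (adjusted p = 0.623). miR-100 fell by 0.77 but stood 0.03 higher in the deposited table. In the miR-181 family 5 of 6 names fell, and 6 adjusted over the list alone, with a median of -1.11, or -1.35 relative to all probes. All 3 names of the epithelial miR-200 family fell, and 3 adjusted over the list alone, among them miR-429 by -2.27 ± 0.31 and miR-200a by -1.06 ± 0.27. All 3 names of the group of miR-192, miR-194 and miR-215 fell, and 3 adjusted over the list alone, with a median of -3.20, or -3.44 relative to all probes. Their camera adjusted p was 0.000486, 0.00105, 0.013 and 0.00633 in this order, and for each adjusted p = 0.447 with an estimated correlation. Normexp background correction ended the calls of miR-29d, miR-181c, miR-181d and miR-181a-2*, and scaling by all probes those of miR-125b, miR-125c, miR-99, miR-100, miR-200a, miR-181b and miR-181c.

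The other tested lists gave no camera call between these stages. Of the miR-202 names, 2 of 3 rose, and 2 adjusted over the list alone, where miR-202-3p also fell (adjusted p = 0.0744 over all probes). The list itself had a camera adjusted p of 0.306. In the let-7 family 2 of 15 names rose (let-7i and let-7e) and 2 fell (let-7a* and let-7c-1*), and 1 and 2 adjusted over the list alone. In the miR-17-92 family, tied to proliferation, 3 of 17 fell (miR-19a, miR-19b and miR-18b), and 2 adjusted over the list alone. The granulosa list had 1 rise among 3 names (miR-21), and 1 adjusted over the list alone; its median was -0.57, its mean 0.13 and its test direction up. In the miR-15/16 family 1 of 8 fell (miR-195), and 1 adjusted over the list alone. In the miR-23/24/27 clusters 2 of 8 rose (miR-24 and miR-27a), and 2 adjusted over the list alone. In the miR-30 and miR-26 families 3 of 11 rose (miR-26a, miR-26b and miR-30e), and 3 adjusted over the list alone. Among blood markers, none of the 3 erythroid names passed, also 0 adjusted over the list alone, with miR-451 higher by 1.33 ± 0.60 (adjusted p = 0.0953). Of 8 leukocyte names 2 rose, and 2 adjusted over the list alone, miR-223 by 1.43 ± 0.33 and miR-146a by 1.44 ± 0.23. In the smooth muscle list 1 of 4 names rose (miR-143*), and 1 adjusted over the list alone, and 2 of 7 stromal names rose (miR-199* and miR-199b), and 2 adjusted over the list alone. In the muscle list miR-499 rose, miR-1a and miR-133b fell, and 1 and 3 adjusted over the list alone rose and fell. miR-221 was the 1 of 4 names of its family to rise, and 1 adjusted over the list alone. On leaving out 1 array the calls of miR-1a (immature 1 or 2, mid-vitellogenesis 2), miR-133b (immature 1 or 2, mid-vitellogenesis 2 or 3), miR-24 (any immature array, mid-vitellogenesis 1 or 3) and miR-30e (immature 2, mid-vitellogenesis 2) ended, with a highest adjusted p of 0.0712, 0.0929, 0.0699 and 0.0819, each without immature 2. That of miR-143* ended without immature 1 or mid-vitellogenesis 3, with adjusted p up to 0.0642. That of miR-18b ended without any immature or mature array or mid-vitellogenesis 1 or 3 (adjusted p up to 0.136, without immature 1), and that of let-7e without any immature or mid-vitellogenesis array, late vitellogenesis 1 or mature 2 (adjusted p up to 0.103, without immature 3). The lists with under 3 measured names held miR-122 (liver, 0.53 ± 0.84), miR-128 (neural, 0.20 ± 0.38), miR-462 (0.79 ± 0.34), miR-203a (not well above background on any immature array, at least 1.62-fold higher) and miR-205 (-1.08 ± 0.38). Only miR-205 of these passed (adjusted p = 0.0368), and its call ended on leaving out any of the 3 immature arrays or mid-vitellogenesis 2 or 3, with adjusted p up to 0.102 without mid-vitellogenesis 3. No name of the miR-430 family (29 on the array), which clears maternal mRNAs in fish embryos, or of the miR-183 cluster (11) met the filter.

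**Figure D2:**
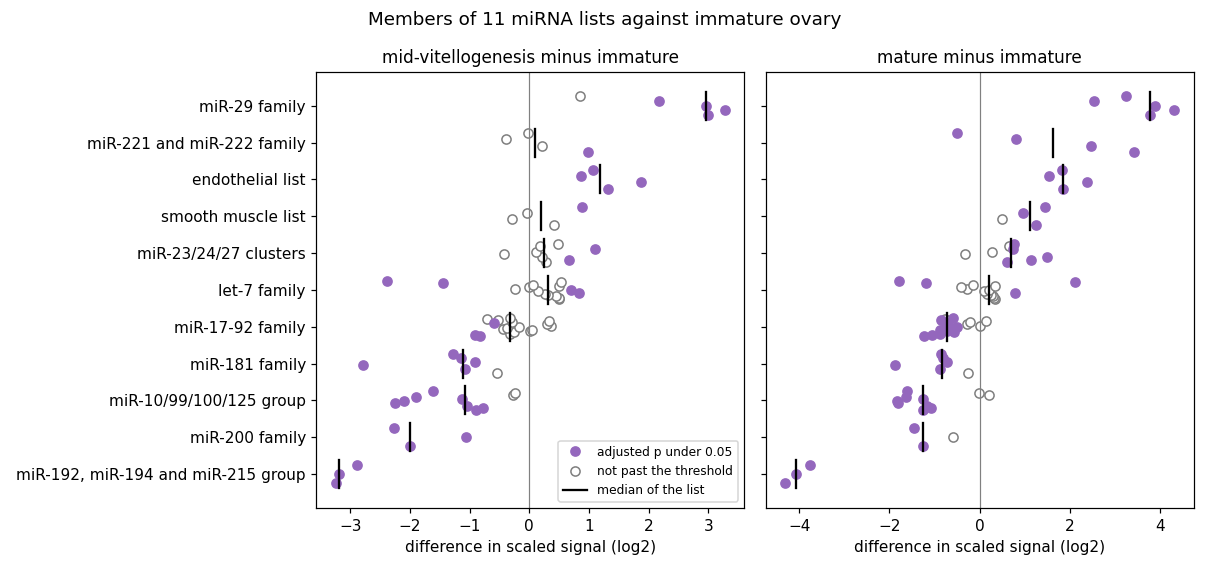
Log2 differences (horizontal axis) of the members of 11 miRNA lists (rows of points) for mid-vitellogenesis minus immature and mature minus immature. Each point is a miRNA name, filled where adjusted p was under 0.05, and black bars are list medians; the median of the miR-29 family was 2.95 and 3.78, and that of the group of miR-192, miR-194 and miR-215 -3.20 and -4.06.

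No single miRNA passed between late and mid-vitellogenesis. miR-202* stood at 13.01 ± 0.58 and 12.30 ± 0.49 (SD, n = 3 each), a difference of -0.71 ± 0.36 (SE, adjusted p = 0.355). miR-29b stood at 9.94 ± 0.05 and 10.13 ± 0.53, and miR-2184 at 9.41 ± 0.05 and 9.21 ± 0.43. The list test placed let-7 (adjusted p = 0.0298), miR-181 (0.0137), the endothelial list (0.00652) and the smooth muscle list (0.00549) higher in late vitellogenesis, with medians of 0.22, 0.23, 0.46 and 0.49. With an estimated correlation their adjusted p was 0.787, 0.447, 0.447 and 0.479. No member of these lists passed over all probes, and adjusted over the list alone only miR-145* of smooth muscle did. With slide as a block the miR-181 and endothelial calls ended. Leaving out mid-vitellogenesis 2 ended the calls of miR-181 (adjusted p = 0.0661), smooth muscle (0.069) and let-7, the last also without late vitellogenesis 1 or 2 (adjusted p up to 0.301). The group of miR-192, miR-194 and miR-215 had no camera call (adjusted p = 0.0706) but a median of -0.95 (-0.88 with names at their bounds), and 2 of its 3 names fell adjusted over the list alone, 0 over all probes. In limma 0 of 681 probes passed, 100 had an unadjusted p under 0.05, and array weights gave 47 (7 higher, 40 lower). Without mid-vitellogenesis array 1, 30 probes passed, all lower in late vitellogenesis and 0 of them named for zebrafish. The mid-vitellogenesis arrays left in that fit had the most probes well above background, 938 and 790, and array 2 among them had 7% of negative controls well above background, against at most 3.6% elsewhere. Mid-vitellogenesis array 1 correlated with the late vitellogenesis arrays with a mean r of 0.977 across probes and with the other mid-vitellogenesis arrays with 0.949.

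Post-vitellogenesis differed from late vitellogenesis in few miRNAs. miR-2184 rose by 1.65 ± 0.29 (SE), from 9.21 ± 0.43 (SD, n = 3) to 10.87 ± 0.03 (n = 2), with adjusted p = 0.0273. miR-181a* rose by 1.33 ± 0.19, from 5.44 ± 0.12 to 6.77 ± 0.00, with adjusted p = 0.00413. Only 3 probes passed, all higher. The remaining one, named here after its values were seen, was a dim probe for frog miR-144, an erythroid miRNA, with 1.37 ± 0.18 (adjusted p = 0.00407), while the brightest miR-144 probe differed by 2.57 ± 1.04 (adjusted p = 0.249). The miR-29 and leukocyte lists were higher as groups, with medians of 0.95 and 1.02 (adjusted p = 0.0102 and 0.0035), and let-7 and the miR-10, miR-99, miR-100 and miR-125 group lower, with medians of -0.24 and -0.27 (adjusted p = 0.00628 and 0.00549). With an estimated correlation the adjusted p was 0.52, 0.571, 0.71 and 0.447, and with slide as a block these 4 calls ended. The miR-29 and leukocyte calls also ended without post-vitellogenesis 1 (adjusted p = 0.177 and 0.114), let-7 without late vitellogenesis 2 or post-vitellogenesis 2 (up to 0.467), and the miR-10, miR-99, miR-100 and miR-125 group without late vitellogenesis 2 (0.0516). The erythroid list moved further up, with a median of 1.64, but had no call (adjusted p = 0.206), and its miR-451 and miR-144 were highest on post-vitellogenesis array 1. Blood content as a source of the leukocyte rise was not tested. Members past the threshold numbered 0 over all probes in each, and adjusted over the list alone 4 of miR-29 and 4 of the leukocyte list rose and 1 of let-7 (let-7c) fell. At an unadjusted p under 0.05 there were 117 probes. Slide as a block gave 5 probes (4 higher, 1 lower), in which the change of miR-181a* was 1.39 and passed and that of miR-2184 was 2.01 and missed the threshold. A fit to these 2 stages alone gave 0 probes, so neither named call held there. Slide 2 alone also gave 0, with a single late vitellogenesis array on it and thus little power. Without post-vitellogenesis array 2 the count was 34, and without array 1 it was 5, in fits where the lone array left is assumed to vary like those of the other stages. The miR-2184 call also ended on leaving out immature 1, any mid-vitellogenesis array, late vitellogenesis 2 or 3, post-vitellogenesis 1 or mature 3, with adjusted p between 0.0503 and 0.146, and no call was left with scaling by all probes or normexp.

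Mature ovary, in which oocytes resume meiosis, was compared with post-vitellogenesis. miR-221, whose family targets the Kit receptor and the cell cycle inhibitor p27, rose by 1.80 ± 0.28 (SE), from 8.41 ± 0.63 (SD, n = 2) to 10.21 ± 0.06 (n = 3), with adjusted p = 0.00676. The probe for fly miR-289-5p rose by 1.80 ± 0.32, with 1 of 2 post-vitellogenesis arrays above background (adjusted p = 0.0116). miR-202 changed by -1.50 ± 0.34, from 8.52 ± 0.28 to 7.03 ± 0.07 (adjusted p = 0.0367), whereas miR-202* differed by -0.13 ± 0.40. The names miR-3082-5p, miR-574-5p, miR-101a and the hypoxia-responsive miR-210 were lower by -1.77 ± 0.36, -1.50 ± 0.35, -1.08 ± 0.26 and -0.83 ± 0.18 (adjusted p = 0.0263, 0.0421, 0.049 and 0.0367). The list test placed the miR-221 and miR-222 family higher (adjusted p = 0.00261), with 1 of 4 names rising over all probes and 3 adjusted over the list alone. It also placed the miR-10, miR-99, miR-100 and miR-125 group higher (0.00652, 0 members adjusted over the list alone) and the erythroid and leukocyte lists lower (0.028 and 0.00549, with 3 and 0 names that fell adjusted over the list alone and 0 over all probes). With an estimated correlation the adjusted p was 0.447, 0.447, 0.6 and 0.6, and the erythroid call ended with slide as a block. Without post-vitellogenesis 1, the array with the highest miR-451 and miR-144, the erythroid and leukocyte calls ended (adjusted p = 0.245 and 0.308), the erythroid one also without post-vitellogenesis 2 or mature 3. The call of the miR-221 and miR-222 family ended without post-vitellogenesis 2 (0.0606), and that of the miR-10, miR-99, miR-100 and miR-125 group without either post-vitellogenesis array (up to 0.065).

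Of 681 probes 19 passed between mature ovary and post-vitellogenesis, 6 higher and 13 lower. The share of higher calls depended on the scaling, with 11 higher and 11 lower under quantile normalization and 6 higher and 5 lower under median scaling. With slide as a block 12 probes passed (6 higher, 6 lower), with miR-221 changing by 1.77, miR-289-5p by 1.74 and miR-202 by -1.53 past the threshold. Of the 7 named calls 4 passed with the block, and miR-574-5p by -1.68, miR-101a by -0.99 and miR-210 by -0.87 fell short of it (adjusted p = 0.0704, 0.147 and 0.0733). A fit to these 2 stages alone gave 0 probes, as did slide 2 alone with 2 arrays per stage and scaling by all probes, so no named call held in these fits. The calls of miR-202, miR-3082-5p, miR-574-5p, miR-101a, miR-210 and miR-289-5p each ended on leaving out some single arrays. The highest adjusted p in these fits was 0.137 for miR-202 and 0.137 for miR-210 without post-vitellogenesis 2, and 0.167, 0.258, 0.277 and 0.0668 for miR-3082-5p, miR-574-5p, miR-101a and miR-289-5p without post-vitellogenesis 1. That of miR-221 held on leaving out any 1 array but also ended with no filter. The count was 34 without post-vitellogenesis 2, where the lone array left is assumed to vary like the others, 10 without immature 1, 11 without immature 2, 12 without late vitellogenesis 1, 10 without late vitellogenesis 2, and 7, 8 and 11 without mature 1, 2 and 3.

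Mature and immature ovary mark the ends of the series. miR-2184 rose by 4.51 ± 0.26 (SE), from 6.03 ± 0.43 to 10.54 ± 0.28 (SD, n = 3 each), with adjusted p = 1.81e-07. miR-29b rose by 4.31 ± 0.35, miR-29a by 3.78 ± 0.21, miR-221 by 3.42 ± 0.25 and miR-222 by 2.47 ± 0.27. miR-499, which lies in a myosin gene, rose by 3.42 ± 0.50 with 1 of 3 immature arrays above background, miR-7 by 2.76 ± 0.27, miR-21 by 2.48 ± 0.22 and miR-202* by 2.70 ± 0.36. miR-192 changed by -4.31 ± 0.44 (adjusted p = 1.08e-05), from 9.38 ± 0.91 to 5.07 ± 0.49. miR-196a changed by -4.10 ± 0.40, with 1 of 3 mature arrays above background, and miR-181a* by -1.89 ± 0.17. miR-194 was not well above background on any mature array and was at least 11.1-fold lower. In total 302 probes passed, 163 higher and 139 lower in mature ovary, for 128 names (63 higher, 65 lower), 88 of them with more than a 2-fold difference. The median of all probes was 0.25 higher in mature ovary. The balance depended on the processing, with 103 higher and 55 lower under normexp, 141 and 156 under quantile normalization and 133 and 161 with the deposited values. Mature and immature arrays shared no slide, so the slide block links them only through the late vitellogenesis arrays, which lie on 2 slides. On slide 2 that link is late vitellogenesis 3 alone, marked for evaluation with a median spot variation of 38.1%. Mature 3, alone on slide 3, does not inform this contrast with the block. Whether a call that ended with the block reflects slides or that 1 late array cannot be told apart. With slide as a block 136 probes passed (82 higher, 54 lower), of which 128 were among the 302 and in the same direction. Of the 84 calls among the named miRNAs 31 passed with the block, including those of the miRNAs named so far in this comparison. The block estimates were 5.04 for miR-2184, 3.39 for miR-29b, 3.24 for miR-221, 1.94 for miR-21, -3.85 for miR-192 and -4.78 for miR-196a.

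The calls of several of the largest differences between mature and immature ovary ended with slide as a block, where SEs were larger. The differences of miR-1937c (-3.21 ± 0.58, and -3.06 ± 1.19 with the block) and miR-29b-1* (at least 7.53-fold higher, and 3.42 ± 1.18 on the log2 scale with the block) stayed about as large. Those of miR-1260b (-3.28 ± 0.75, then -2.15 ± 1.36), miR-1386 (-2.75 ± 0.67, then -2.21 ± 1.31), miR-458 (-2.33 ± 0.34, then -1.39 ± 0.54), miR-1260 (-2.29 ± 0.65, then -1.58 ± 1.29) and miR-4299 (2.74 ± 1.00, then 0.82 ± 1.94) were smaller with the block. The call of miR-4299 also ended without any 1 of the immature or mature arrays, mid-vitellogenesis 2 or late vitellogenesis 1 (adjusted p up to 0.104, without immature 3), and that of miR-1260 without mature 3 (adjusted p = 0.0509). The calls of miR-1599 (-3.00 ± 0.82) and miR-202 (1.14 ± 0.30) ended with no filter on dim probes, and normexp ended those of miR-196a, miR-194 and miR-202. The probe for mouse miR-202-3p was at least 2.85-fold lower in mature ovary, a call that ended with slide as a block (-2.12 ± 0.83) and turned to 0.05 higher with normexp.

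By list, all 5 names of the miR-29 family were higher in mature ovary, and 5 adjusted over the list alone, with a median of 3.78 (3.53 relative to all probes), and 3 passed with slide as a block. All 4 endothelial names, each a name of miR-126, rose, and 4 adjusted over the list alone, miR-126 by 2.38 ± 0.22, and 3 passed with the block. In the miR-10, miR-99, miR-100 and miR-125 group 8 of 10 fell, and 8 adjusted over the list alone, 4 with the block, among them miR-125b by -1.25 ± 0.20 and miR-10a by -1.83 ± 0.25. In the miR-181 family 5 of 6 fell, and 5 adjusted over the list alone, 3 with the block. All 3 names of the group of miR-192, miR-194 and miR-215 fell, and 3 adjusted over the list alone, also 3 with the block. Camera gave adjusted p = 0.00134, 0.00549, 0.00134, 0.00652 and 0.00549 for these lists, each with adjusted p = 0.447 with an estimated correlation, and all 5 calls held with the block. The miR-17-92 family showed 12 of 17 names lower, and 13 adjusted over the list alone, with a median of -0.72 (-0.59 with names at their bounds), miR-19b by -1.23 ± 0.21 among them. Its camera call (adjusted p = 0.0018, and adjusted p = 0.447 with an estimated correlation) ended with slide as a block, where 0 of its names passed, and 11 of the 12 calls kept their sign with it. Some differences stayed about as large with the block, as miR-25 (-0.88, then -0.98 ± 0.43), miR-92a-3p (-0.85, then -1.25 ± 0.45) and miR-92a (-0.88, then -0.74 ± 0.51), so that their calls ended with the larger SE, while others came near 0, as miR-17a (-0.72, then -0.06 ± 0.30). Normexp turned miR-18b, miR-92a-3p, miR-17a*, miR-181c, miR-181d and miR-181a-2* to slightly higher values, and the slide block did so for miR-18b. Leaving out immature 1 ended 7 of the 12 calls of the miR-17-92 family, those of miR-92a (adjusted p = 0.0539), miR-20a (0.0933), miR-17a (0.0508), miR-106 (0.132), miR-17-5p (0.155), miR-18b (0.0674) and miR-17a* (0.0589). Of these, miR-92a also ended without mature 3, miR-17a* without immature 3, miR-106 without mature 1 or 2, miR-20a without immature 2 or any mature array, and miR-17-5p without those 4 arrays, mid-vitellogenesis 1 or 3 or late vitellogenesis 1. Leaving out mature 2 ended the call of miR-181a-2* (0.0679).

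The remaining lists had no camera call in mature against immature ovary, and the counts after each comma are adjusted over the list alone. In the miR-200 family 2 of 3 fell, 2 adjusted over the list alone, and in the miR-202 list 2 rose and 1 fell, 2 and 1 adjusted over the list alone. In the miR-221 and miR-222 family 3 rose and 1 fell (miR-222b), 3 and 1 adjusted over the list alone. In the miR-23/24/27 clusters 5 of 8 rose, 6 adjusted over the list alone, led by miR-27c with 1.49 ± 0.19. In smooth muscle 3 of 4 rose, 3 adjusted over the list alone, among them miR-145 by 1.26 ± 0.31 and miR-143 by 0.97 ± 0.24. In the miR-30 and miR-26 families 4 of 11 rose, 4 adjusted over the list alone, and in the stromal list 2 of 7, 2 adjusted over the list alone. The leukocyte list had 2 rises among 8, 2 adjusted over the list alone, and the erythroid list 0 of 3, 0 adjusted over the list alone. The let-7 family had 2 rises and 2 falls among 15, 1 and 2 adjusted over the list alone, the largest being let-7a-1* with 2.11 ± 0.28. The miR-15/16 family had 2 rises and 1 fall among 8, 2 and 1 adjusted over the list alone. In the granulosa list miR-21 rose, and adjusted over the list alone 1 rose and 1 fell. The muscle list had 1 rise (miR-499) and 1 fall (miR-133b), 1 and 1 adjusted over the list alone. Among lists with under 3 measured names, miR-203a was at least 4.22-fold higher, a call that ended with slide as a block (1.08 ± 1.01), and miR-205 (-0.43 ± 0.38), miR-128 (-0.03 ± 0.38), miR-462 (0.55 ± 0.34) and miR-122, not well above background on any mature array and at least 2.15-fold lower, did not pass.

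Many of the calls in these remaining lists ended with slide as a block or on leaving out single arrays. With slide as a block 0 of the calls passed in the lists of smooth muscle (3 calls), miR-30 and miR-26 (4), stroma (2), leukocytes (2) and miR-15 and miR-16 (3). In the clusters of miR-23, miR-24 and miR-27 1 of 5 passed (miR-27c), in the let-7 family 2 of 4, in the miR-200 family 1 of 2, in the miR-221 and miR-222 family 2 of 4, and in the muscle list 1 of 2. All of these calls kept their sign, and some their size, as miR-145 with 1.28 ± 0.63 and miR-143 with 1.32 ± 0.45, while miR-27e (0.05 ± 0.35) and miR-16a (0.15 ± 0.38) came near 0. On leaving out 1 array the call of let-7e ended for all immature, mid-vitellogenesis and late vitellogenesis arrays and mature 2 and 3, with adjusted p up to 0.206. Those of miR-26a (immature 2 or 3, mature 2 or 3), miR-26b and miR-30d* (both immature 2 or 3, mature 3) ended with adjusted p up to 0.0694, 0.0731 and 0.0796. Those of miR-15a (immature 2 or 3, any mature array), miR-16a (immature 2 or 3, mature 1) and miR-195 (immature 1, mature 2) ended with up to 0.107, 0.0755 and 0.0539. Those of miR-27a (immature 2, mature 1) and miR-27e (immature 2, mature 3) ended with up to 0.0662 and 0.0607, and that of miR-223 (immature 1 or 3, mature 1 or 3) with up to 0.0961. Those of miR-133b (immature 1 or 2, mature 2 or 3) and miR-222b (immature 1, mature 2 or 3) ended with up to 0.0846 and 0.0727.

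**Figure D3:**
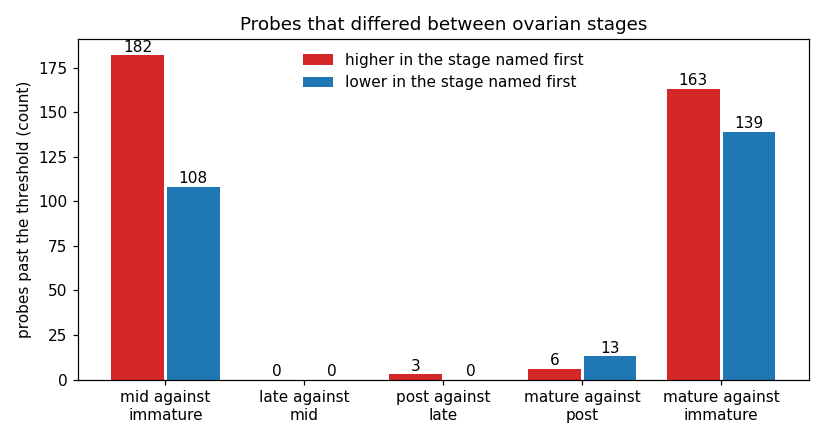
Number of probes (vertical axis, from 0) past an adjusted p of 0.05 in each of the 5 comparisons (horizontal axis), with bars for probes higher and lower in the later stage. Mid-vitellogenesis against immature had 182 higher and 108 lower probes and late against mid-vitellogenesis had 0.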

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

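The fits on zebrafish-named probes, without the arrays of uneven spots, with the median of the spots or within 1 slide were chosen after seeing the data. All other alternatives were planned. Outside the fits that leave out 1 array, the 178 named results gave 2797 values, of which 2423 kept direction and side of the threshold, 362 lost the call and 12 reversed. On leaving out 1 array 2293 of 2492 kept both and 199 lost the call. Scaling by the 75th percentile of all probes gave 188 probes in the F-test, 0 in post-vitellogenesis against late vitellogenesis, 0 in mature against post-vitellogenesis and 190 in mature against immature. Quantile normalization gave 2 for late against mid-vitellogenesis, and median scaling 11 for mature against post-vitellogenesis. With normexp on the spot median (in place of the planned spot mean) the F-test gave 165, and the contrasts 135 (mid-vitellogenesis against immature), 0 (post-vitellogenesis against late), 1 (mature against post-vitellogenesis) and 158 (mature against immature). With no filter on dim probes the counts were 157, 150, 3 and 182 for the F-test, mid-vitellogenesis against immature, mature against post-vitellogenesis and mature against immature. With 1 value per name, thus fewer tests, they were 137, 122, 3 and 126 by the brightest probe and 132, 126, 5 and 124 by the mean. The zebrafish-named probes, also fewer, gave 130, 115, 9 and 132, and 15 for post-vitellogenesis against late. The deposited values gave 1 and 4 for post-vitellogenesis against late and mature against post-vitellogenesis, array weights 1 and 7 with 47 for late against mid-vitellogenesis, and the slide block 5 and 12 with 136 for mature against immature. For post-vitellogenesis against late and mature against post-vitellogenesis, fits to the compared stages alone gave 0 each and fits within slide 2 gave 0 each, with fewer arrays (1 of late vitellogenesis on slide 2). Without the 2 arrays of uneven spots post-vitellogenesis against late gave 6. Of 24 list calls 0 held with an estimated correlation in camera, and fry called 21 of the 95 pairs. Apart from the smaller sets of probes or arrays, the cause was not tested. In mature against immature normexp reversed miR-202-3p (0.046), miR-18b (0.0017), miR-92a-3p (0.36), miR-17a* (0.40), miR-195 (0.39), miR-181c (0.0014), miR-181d (0.30), miR-181a-2* (0.36), miR-133b (0.040) and miR-222b (0.40), and the slide block reversed miR-18b (0.049). The deposited values reversed miR-100 in mid-vitellogenesis against immature (0.033). On leaving out 1 array the counts ranged from 231 to 389 for the F-test, from 222 to 311 for mid-vitellogenesis against immature, from 0 to 30 for late against mid-vitellogenesis, from 2 to 34 for post-vitellogenesis against late, from 7 to 34 for mature against post-vitellogenesis, from 251 to 320 for mature against immature and from 20 to 25 for list calls. Late against mid-vitellogenesis gave 30 without mid-vitellogenesis 1, and post-vitellogenesis against late 34 and 5 without post-vitellogenesis 2 and 1, where the lone array left is assumed to vary like the others. Mature against post-vitellogenesis gave 34 without post-vitellogenesis 2, 10 and 11 without immature 1 and 2, 12 and 10 without late vitellogenesis 1 and 2, and 7, 8 and 11 without mature 1, 2 and 3. The share of probes above background, 7.69% on average, limits which miRNAs could be seen.

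Replicate numbers were not taken to pair samples. After stage means were removed, the 26 pairs of arrays with the same number correlated between -0.297 and 0.483 across probes with a median of -0.023, against 0.038 for the other pairs, and 6 of the 26 exceeded 0.1. For 8 of the 14 arrays, thus not for every one, the best partner had the same number, a hint from the data and not from the design. With replicate number as a block 7 probes passed in mature against post-vitellogenesis, 6 higher and 1 lower, against 6 higher and 13 lower without it, so most of the lower calls ended, and the cause was not tested.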

Other observations

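All tests in this part were chosen only after the result was seen, except the test of signal compression for miR-202 and that of zebrafish-named probes for mid-vitellogenesis array 1, whose predictions were written before.

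Some miRNAs stood apart on single arrays. miR-204, known from retina and other epithelia, reached 11.66 on immature 2 with its brighter zebrafish probe and 10.56 with the other, and the next highest array of the brighter probe, post-vitellogenesis 1, had 7.92. The brighter probe of miR-199a-3p, a miRNA of mesenchyme, read 9.98 on post-vitellogenesis 1 and at least 12.43 elsewhere, while the other probe of that name read 12.75 on the same array. The hepatocyte miR-122 read 6.98, 4.84 and 3.58 on the 3 immature arrays and 6.52, 6.83 and 3.64 on the 3 mid-vitellogenesis arrays, against at most 3.74 on the others. The erythroid miR-451 and miR-144 were highest on post-vitellogenesis 1, with 16.47 and 12.48, and miR-144 was lowest on immature 2 with 5.03.

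Other splits of the same arrays were counted. For the F-test 1 of 100 assignments of the 14 arrays to stages, the real one, gave as many probes as 328. The highest other gave 262. A random assignment thus seldom reached that count, though 100 assignments cannot show how seldom. The count also does not tell which stages differ. The contrasts of 3 against 3 arrays allow 10 splits, too few for a share under 0.05. As many probes as in the real split came from 1 of the 10 splits in mid-vitellogenesis against immature (290, highest other 1) and from 1 in mature against immature (302, highest other 0). In late against mid-vitellogenesis all 10 did (0, highest other 3).

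miR-202 fell more than miR-202* at maturity. miR-202 itself changed by -1.38 ± 0.24 (SE, two-sided exact permutation p = 0.00606, the smallest that the 165 splits can give). Its mean was 7.03 ± 0.07 (SD, n = 3) in mature ovary and 8.41 ± 0.40 (n = 8) over mid-vitellogenesis to post-vitellogenesis. miR-202* changed by -0.37 ± 0.38 (exact permutation p = 0.364), and the difference of the arms by -1.01 ± 0.37 (exact permutation p = 0.0364). The difference of the arms overlapped between stages, with -5.11 on mid-vitellogenesis 2 against -4.83, -5.04 and -5.67 on the mature arrays, so it does not set mature ovary apart from every earlier array. Under compression of the bright miR-202* signal its dimmest probe would fall as much as miR-202. The changes differed by -1.02 ± 0.49 (exact permutation p = 0.0667). That is little more than the 2 SE set beforehand, and the exact p was not under 0.05, so compression is not excluded. Within slide 2 the difference of the arms changed by -1.01 ± 0.42 (exact permutation p = 0.2, with 2 and 3 arrays and 10 splits). Without the 2 arrays of uneven spots it changed by -1.04 ± 0.43 (exact permutation p = 0.0714). Both exceed 2 SE, but neither exact permutation p was under 0.05. The 3 earlier arrays on slide 2 were, however, those marked for evaluation, so slide and uneven spots were not tested apart. Neither is excluded as the source. The mouse miR-202-3p probe was not part of this comparison. It was lower in mature than in immature ovary, where miR-202 was higher, although that call ended with slide as a block. As a hypothesis, the arms may be processed or kept unequally, which was not tested.

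miR-192, miR-194 and miR-215, markers of gut and kidney epithelium, were highest in immature ovary, and higher on immature 1 than on immature 3 by 1.79, 1.90 and 1.88. The other 34 names that fell more than 2-fold had a median difference between these arrays of 0.20 (SD 0.56), and 0 of them differed as much. This argues against 1 other tissue, unequal between these 2 arrays, as the shared source of all miRNAs that fell. Tissue present in like amounts on both arrays would leave no such difference, so it was not tested. The scaling is not a likely source of the fall of miR-192, miR-194 and miR-215. Their smallest median fall over all scalings and background corrections was -2.10. For these 3 miRNAs alone, another tissue and ovarian cells that share their control cannot be told apart, since their differences lay within 0.11 of one another and either would give that. Probe sequences were not analysed, so it also stays open whether the 3 names read separate trout miRNAs. Between these 2 arrays some markers of liver and muscle ran the same way. miR-122 stood at 6.98 on immature 1 and 3.58 on immature 3, and miR-133b and miR-1a were higher on immature 1 by 1.47 and 0.99. Across stages, however, miR-122 averaged 0.53 higher in mid-vitellogenesis than in immature ovary, without a call. miR-499 of the muscle list was 2.12 higher there. Tissue carried along and the stage itself both stay open as sources.

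Mid-vitellogenesis array 1 correlated better with the late vitellogenesis arrays than with its own stage, by 0.027 in r across the 681 probes. Of the late arrays 0 lay nearer to mid-vitellogenesis 2 and 3 than to their own stage. However, mid-vitellogenesis 2 and 3 stood apart on the second principal component, with scores of 15.1 and 11.8 against at most 6.36 elsewhere. A true mid-vitellogenesis array might thus not lie near them either, so a swap with a late array is not excluded. On the 215 zebrafish-named probes the difference in r was -0.0025 (bootstrap SD 0.0036), so the nearness of mid-vitellogenesis 1 to the late arrays may come from probes named for other species. The 30 probes lower in late vitellogenesis without this array, led by miR-2976, not well above background in late vitellogenesis, and miR-1224 (-4.64), included 0 zebrafish-named ones, and the high background calls on mid-vitellogenesis 2 (7% of negative controls) were not tested as their source. A single wrong label cannot be told apart from a sample late in its stage, since the mean r of 0.977 with the late arrays matched the 0.972 among them. Both readings rest on the 681 probes together. The zebrafish-named probes alone did not place mid-vitellogenesis 1 nearer to the late arrays.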
